A study of Homo sapiens with 4 samples.

How the data were processed

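Whole-genome bisulfite sequencing was done on 4 libraries of IMR-90 fibroblasts, 2 from cells with an empty lentiviral vector and 2 from cells with BRAF V600E. Bisulfite turns unmethylated cytosines into uracil, which is read as thymine, while methylated cytosines are read as cytosine. Per the labels' protocols, DNA was converted with a Zymo EZ DNA Methylation-Gold kit and sequenced as 90 bp paired-end reads on a Illumina HiSeq instrument. The submitters' processing notes name FastQC 0.10.0, Trim Galore 0.3.0, Bismark 0.10.1, Bowtie2 2.1.0 and the genome build hg19. Whether duplicate reads were removed is not given in the sources used here, so calls may not come from independent molecules, and intervals from calls cover counting error only.

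The deposited values are whole-number counts of methylated and of unmethylated calls per library at each listed cytosine of a CpG, not normalized, with the 2 strands on separate rows, per the file headers and the values themselves. The table held 55429156 rows, including rows for the lambda phage and the mitochondrial genome, and 0 value columns that could not be tied to a sample. Positions were counted from 0 and are printed here counted from 1. The calls of both strands were added: 27025474 CpGs on the autosomes and X had both strands listed and 1349172 had 1. Unconverted lambda cytosines, a measure of incomplete conversion, were 0.435% and 0.307% of calls in the vector libraries and 0.368% and 0.292% in the BRAF V600E libraries (Wilson 95% intervals 0.433 to 0.438, 0.304 to 0.309, 0.366 to 0.371 and 0.290 to 0.294). Chromosome Y was left out.

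Groups were taken from the sample titles. Designs, tests, thresholds, gene lists and alternatives were fixed before the data were examined, except where this part or the closing parts say otherwise. The plan did not hold the CpG density classes, the cluster classes by level with their counts of change, or the comparison of library pairs. Nor did it hold the placement tests of called windows or the differences with CpGs matched. Genome-wide levels, CpG-dense clusters and domains were compared as 1 value per library with an exact two-sided permutation test over the 6 ways to assign 2 of 4 libraries, whose smallest p is 0.333, so that no such comparison could reach 0.05. CpG-dense clusters were runs of at least 20 listed CpGs at most 50 bp apart that span at least 200 bp. Partially methylated domains were 100 kb bins with a mean level of all 4 libraries under 65% outside clusters, and highly methylated domains those of at least 75%.

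Single regions were windows of 1 kb (at least 3 CpGs and 20 calls in each library), clusters (at least 20 calls) and bins of 100 kb (at least 100 calls). The methylated and unmethylated calls of each region were fitted with a quasi-binomial logistic model, and the dispersion of each region was squeezed across regions with limma 3.58.1 in R 4.3.3. A region was called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of the group means of at least 10 points (5 for bins). Adjusted p-values in the report come from this limma-moderated model unless another test is named. The median 1 kb window held 101 calls per library and had a replicate SD of 3.24 points, the median cluster held 420 calls with 1.18 points, and the median bin had 0.753 points. Scripts used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

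The test was tried on simulated calls for the real regions with 200 regions lowered by known amounts, 50 of each size. The lowered regions were drawn from those with a mean level above 50%, so no cluster under 10% was among them. The simulated dispersion was the same for every region of a kind. Among 2401593 windows it recovered 0% of those lowered by 10 points, 14% at 20 points, 28% at 30 points and 56% at 40 points, and called 0 unchanged windows. That 0 holds for simulated calls only: dividing the real libraries across the groups gave 29 and 122 called windows, of which 29 and 115 had 20 or more CpGs, so adjusted p-values of CpG-rich windows do not set the groups apart from other divisions. Among 71228 clusters it recovered 10%, 72%, 90% and 98% at the same sizes. Among 28475 bins it recovered 32% at 5 points and 96% at 10 points. At the smallest size the median fitted difference was -9.48 points for windows, -9.51 for clusters and -4.85 for bins. These fall short of the difference that a call needs, so the cutoff itself limits recovery at that size.

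Regions are named by position. For 1 kb windows and clusters the rule took the 10 with the largest difference in each direction among those past the threshold whose vector values do not overlap the BRAF V600E values, and where none passed in a direction, the 3 with the smallest p there. The same was done for bins. No annotation of hg19 was used, so the planned tests of promoters, gene bodies and gene lists, and the planned comparison of BRAF exons with introns, were not run. A RefSeq table of assembly GRCh38.p14 served only for gene names and their chromosomes.

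Alternatives were the edgeR 4.0.16 negative binomial model for methylated and unmethylated counts, limma on log2 ratios with a pseudocount of 1, the replicate number as a block, each library left out, other minimum differences, coverage minimums and region sizes, the genome-wide difference set to 0, and CpGs in the top 0.1% of summed calls left out. Alternatives chosen after seeing the data were equal weights for each CpG in all libraries (its lowest depth among the 4), dispersions squeezed towards a trend in depth, crossed pairing, thinning to equal calls, removal of windows with excess calls, and correction for unconverted lambda cytosines.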

Results

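DNA methylation was measured by whole-genome bisulfite sequencing in IMR-90 cells, an established line of diploid human fetal lung fibroblasts grown at 3% oxygen. The comparison was between 2 groups of 2 libraries each. The control libraries came from cells that carried an empty vector, and the others from cells given BRAF V600E, a constitutively active form of a kinase of the MAPK pathway. BRAF V600E drives fibroblasts into oncogene-induced senescence, a lasting arrest of the cell cycle, which was not itself measured here. The vector libraries held 432751227 and 399970514 CpG calls on the autosomes and X, and the BRAF V600E libraries 364039378 and 340269505. Positions are those of the hg19 build. A CpG on the autosomes was covered by a mean of 15.4 and 14.2 calls in the vector libraries and of 12.8 and 12.0 calls in the BRAF V600E libraries. Nothing in the labels says whether the 2 libraries of a group came from separate infections, so the spread between libraries may be technical. The p-values of single regions set a group difference against that spread after it was squeezed across regions. Fisher's and binomial tests count windows, and their p-values do not measure the spread between libraries.

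The first question was whether BRAF V600E cells differed from controls in their overall CpG methylation. They differed little. The share of methylated calls on the autosomes was 67.90% ± 0.007 (SD, n = 2) in vector cells and 68.31% ± 0.005 (SD, n = 2) in BRAF V600E cells. BRAF V600E was 0.406 points higher, and both of its libraries lay above both vector libraries (exact two-sided permutation test, p = 0.333, the smallest that 2 against 2 libraries allow). With every CpG given the same weight, among the 21028531 autosomal CpGs with at least 5 calls in each library, the levels were 68.90% ± 0.116 and 68.95% ± 0.187 (SD, n = 2 each). That difference of 0.0469 points was smaller than the replicate SD of 0.156 points (exact permutation p = 1). The BRAF V600E libraries held fewer calls in CpG-dense DNA: in windows with 60 or more CpGs per kb they had 0.889 ± 0.153 times their own mean calls per CpG, against 1.11 ± 0.079 in vector libraries (SD, n = 2 each). In windows with 1 to 4 CpGs per kb the values were 0.871 ± 0.038 and 0.675 ± 0.059 (exact permutation p = 0.333 for both classes).

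**Figure D1:**
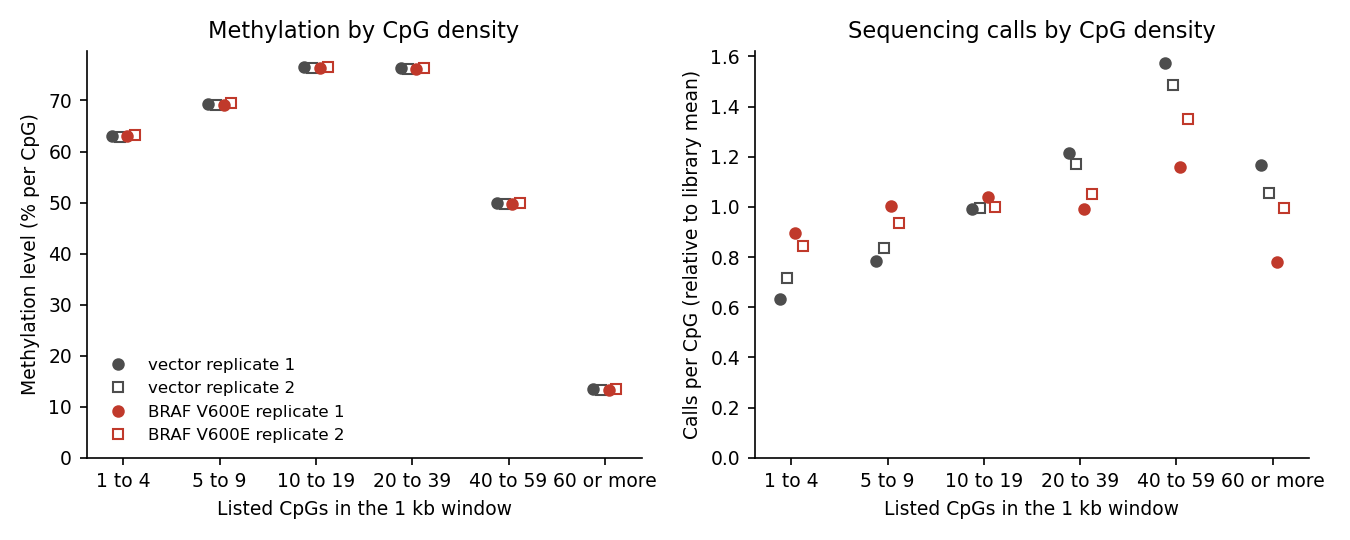
Methylation level per CpG in percent (left) and calls per CpG relative to the mean of the library (right), against the number of listed CpGs in the 1 kb window; each point is 1 of the 4 libraries. The 4 libraries overlap in methylation within every density class, near 63% in the sparsest and 13% in the densest windows, while their calls per CpG differ between the groups in the sparsest and densest classes.

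Gain of methylation at CpG islands, the short CpG-rich stretches found at many promoters, is a feature of a subset of colorectal cancers with BRAF V600E, and the series title names this question. CpG-dense clusters stood in for islands here: runs of at least 20 CpGs at most 50 bp apart. The mean level of these clusters showed no gain. The mean level of 68921 autosomal clusters was 54.33% ± 0.128 in vector cells and 54.33% ± 0.256 in BRAF V600E cells (SD, n = 2 each), a difference of -0.00665 points against a replicate SD of 0.203 points (exact permutation p = 1). The 23049 clusters with a mean level under 10% stood at 2.09% ± 0.093 and 2.07% ± 0.052. Another 33586 of the 68921 had a mean level of 80% or more and little room for gain, at 91.60% ± 0.0996 and 91.58% ± 0.244. Clusters of at least 40 CpGs at most 25 bp apart, of which 10842 were measured, had 8.80% ± 0.155 and 8.82% ± 0.087. Of the 22776 clusters under 10% in both vector libraries, 0 reached 20% in both BRAF V600E libraries, and of the 22666 clusters under 10% in both BRAF V600E libraries, 0 reached 20% in both vector libraries.

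Tested one by one, 0 of 71228 clusters on the autosomes and X passed the threshold in either direction (quasi-binomial model with limma dispersions, adjusted p under 0.05 and a difference of at least 10 points), while 3183 had an unadjusted p under 0.05. Dividing the libraries across the groups gave more such clusters, 3423 and 3614. The edgeR model called 6 clusters, 1 higher and 5 lower in BRAF V600E. In simulated data edgeR also called 2 unchanged clusters, where the quasi-binomial model called 0. Limma on log2 ratios called 0, and it also recovered 0 of the simulated clusters, so its count carries no information. The smallest adjusted p was 0.338, shared by the pair of higher clusters described next. A cluster of 22 CpGs on chromosome 3 (105601439 to 105601675) measured 37.7% ± 5.33 in vector and 68.1% ± 3.68 in BRAF V600E cells (SD, n = 2 each, 198 to 429 calls per library). A cluster of 89 CpGs on chromosome 5 (8457433 to 8458273) measured 21.9% ± 1.13 and 32.1% ± 1.97, and a cluster of 145 CpGs on chromosome 10 (22541366 to 22542739) measured 16.6% ± 0.402 and 21.7% ± 1.21. The clusters with the smallest p in the other direction lay on chromosome X (70287785 to 70288607, 41.8% ± 1.35 and 28.6% ± 4.72), chromosome 14 (69521737 to 69522062, 58.7% ± 6.01 and 39.3% ± 1.27) and chromosome 19 (623989 to 624223, 67.8% ± 2.73 and 50.7% ± 0.726). None of these 6 clusters passed the threshold. In simulated data the test recovered 72% of clusters lowered by 20 points and 10% of those lowered by 10 points, the latter also limited by the 10-point cutoff. Clusters with a low mean level were not among those changed, so these rates do not cover clusters under 10%. Gains and changes smaller than 10 points were not simulated.

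The next comparison concerned the large partially methylated domains, which lose methylation as fibroblasts age through repeated division. These domains were present in both groups. Of the autosomal bins of 100 kb, 8987 (33.3%) had a mean level under 65% outside clusters, and 13148 (48.7%) had at least 75%. Partially methylated domains measured 55.2% ± 0.362 in vector cells and 55.0% ± 0.772 in BRAF V600E cells (SD, n = 2 each), a difference of -0.209 points against a replicate SD of 0.603 points (exact permutation p = 1). Highly methylated domains measured 82.6% ± 0.172 and 82.8% ± 0.3002, a difference of 0.255 points against a replicate SD of 0.245 points (exact permutation p = 0.667). No chromosome had equal-weight levels that separated the groups.

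Among 28475 single 100 kb bins, 0 passed the threshold in either direction (quasi-binomial model with limma dispersions, adjusted p under 0.05 and at least 5 points), with 1884 at an unadjusted p under 0.05. Dividing the libraries across the groups gave 283 and 2864 such bins. The edgeR model called 58 bins, 56 of them higher in BRAF V600E, and limma on log2 ratios called 0. The bins with the smallest p lay on chromosome 1 (156100001 to 156200000, 38.4% ± 0.313 in vector and 43.3% ± 0.036 in BRAF V600E, adjusted p = 0.0574), chromosome 10 (8000001 to 8100000, 41.0% ± 1.05 and 49.6% ± 0.442) and chromosome 15 (41200001 to 41300000, 58.8% ± 0.158 and 64.2% ± 0.741). In the other direction they lay on chromosome 1 (17200001 to 17300000, 65.2% ± 0.291 and 61.8% ± 0.177), chromosome 17 (73400001 to 73500000, 75.9% ± 0.412 and 72.8% ± 0.410) and chromosome 19 (37700001 to 37800000, 76.0% ± 0.282 and 73.8% ± 0.042). None of these 6 bins passed the threshold. Without vector replicate 2 the model called 6 bins, without BRAF V600E replicate 1 it called 10, and without BRAF V600E replicate 2 it called 356, of which 350 were higher in BRAF V600E. With each CpG given the same weight in all libraries, 0 bins were called with 4 libraries and 0 without BRAF V600E replicate 2.

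At the scale of 1 kb a small number of windows was called, and most of them were lower in BRAF V600E cells. In simulated data the test recovered 0% of windows lowered by 10 points, a rate that the 10-point cutoff also limits, and 14% of those lowered by 20 points. The count of calls therefore does not bound the number of windows that differ. Of 2401593 windows, 233 passed the threshold (quasi-binomial model with limma dispersions, adjusted p under 0.05 and at least 10 points): 195 were lower and 38 higher in BRAF V600E. With each CpG weighted alike, 115 were lower and 4 higher. With the replicate number as a block 0 windows were called, with 78606 at an unadjusted p under 0.05. The lower windows had a median difference of -20.6 points, with median levels of 79.7% in vector cells and 53.6% in BRAF V600E cells, and 161 of the 195 had a vector level of at least 60%. They lay on 23 chromosomes and held a median of 13 CpGs. The 38 higher windows held a median of 52.5 CpGs and had a median difference of 12.8 points, with median levels of 34.1% and 50.3%. The edgeR model called 345 windows, 304 lower and 41 higher, and shared 194 of the 233. In simulated data edgeR also called 9 unchanged windows, where the quasi-binomial model called 0. Removing any of the 4 libraries left at most 1 window past the threshold (0 without vector replicate 1, 1 without vector replicate 2, 0 without BRAF V600E replicate 1 and 0 without BRAF V600E replicate 2). These fits had 93638 to 103191 windows at an unadjusted p under 0.05. Limma on log2 ratios called 0, with 119587 at an unadjusted p under 0.05. Dividing the same libraries across the groups gave 29 windows (17 in one direction and 12 in the other) and 122 windows (50 and 72), so the 38 higher windows were no more than a division across the groups gave. At an unadjusted p under 0.05 in the quasi-binomial model, BRAF V600E against vector gave 115142 windows and these divisions 113806 and 121258. At a difference of at least 20 points the counts were 104 for BRAF V600E against vector (101 lower, 3 higher) and 3 and 13 for the other divisions.

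**Figure D2:**
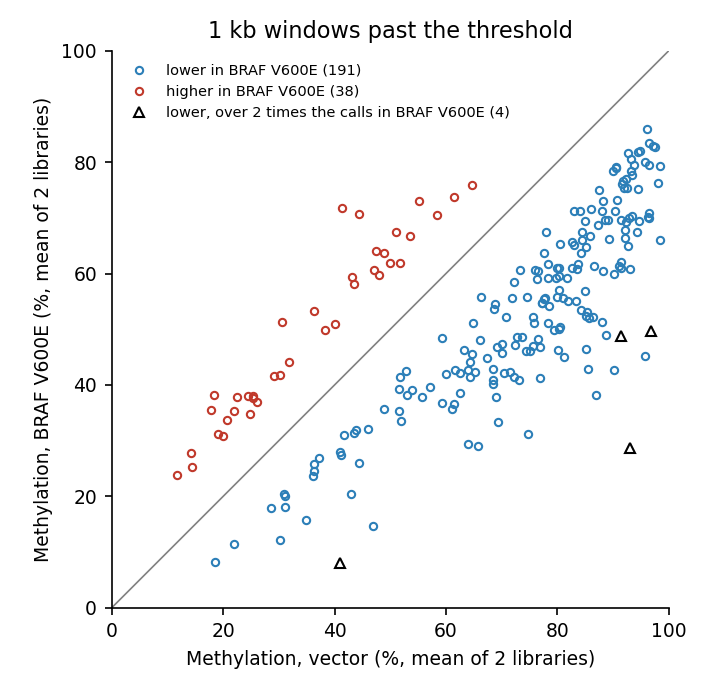
Mean methylation of the 2 BRAF V600E libraries against that of the 2 vector libraries, both in percent, for the 233 windows of 1 kb past the threshold; the line marks equal levels and triangles mark the 4 windows with over 2 times the calls in BRAF V600E libraries. The 195 lower windows lie below the line, mostly at vector levels above 60%, and the 38 higher windows lie above it at lower levels.

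The windows with the largest loss included several in which each group's libraries were close together. A window of 15 CpGs on chromosome 1 (159798001 to 159799000) fell from 90.2% ± 2.58 to 42.7% ± 2.17 (SD, n = 2 each, 216 to 366 calls per library, adjusted p = 1.184e-10). A window of 8 CpGs on chromosome 2 (113597001 to 113598000) fell from 86.9% ± 0.792 to 38.2% ± 0.9496, with 104 to 159 calls per library (adjusted p = 3.76e-07). On chromosome 5, a window at 134476001 to 134477000 fell from 85.5% ± 1.14 to 42.9% ± 1.59 (127 to 284 calls), and another at 38828001 to 38829000 from 95.8% ± 5.99 to 45.3% ± 10.2 (42 to 66 calls). A window on chromosome 7 (93787001 to 93788000) fell from 74.7% ± 5.33 to 31.2% ± 1.87 (86 to 116 calls), and one on chromosome 12 (95034001 to 95035000) from 85.1% ± 1.96 to 46.5% ± 8.29 (91 to 209 calls). A window of 4 CpGs on chromosome 3 (160094001 to 160095000) measured 88.7% ± 9.78 and 49.0% ± 5.94 (adjusted p = 0.0316), and lost the call with each CpG weighted alike, although the difference of -39.7 points was then -42.0. The other 3 of the 10 largest decreases in percentage lay within 101 kb of each other on chromosome 7, and the BRAF V600E libraries had over 2 times the calls there. The window at 140534001 to 140535000 measured 93.0% ± 5.86 in vector and 28.7% ± 16.5 in BRAF V600E cells. That at 140494001 to 140495000 measured 96.9% ± 2.02 and 49.7% ± 12.0, and that at 140434001 to 140435000 measured 91.4% ± 2.02 and 48.8% ± 37.1. The last of these lost the call with each CpG weighted alike, at a difference of -38.0 points, and its difference of -42.6 points was -16.4 without BRAF V600E replicate 2 and -68.8 without BRAF V600E replicate 1. Depth-scaled calls were 6.58, 4.14 and 2.34 times those of the vector libraries in these 3 windows. Added unmethylated calls would lower these percentages without any loss at the cells' own copies, so a loss cannot be read from them.

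**Figure D3:**
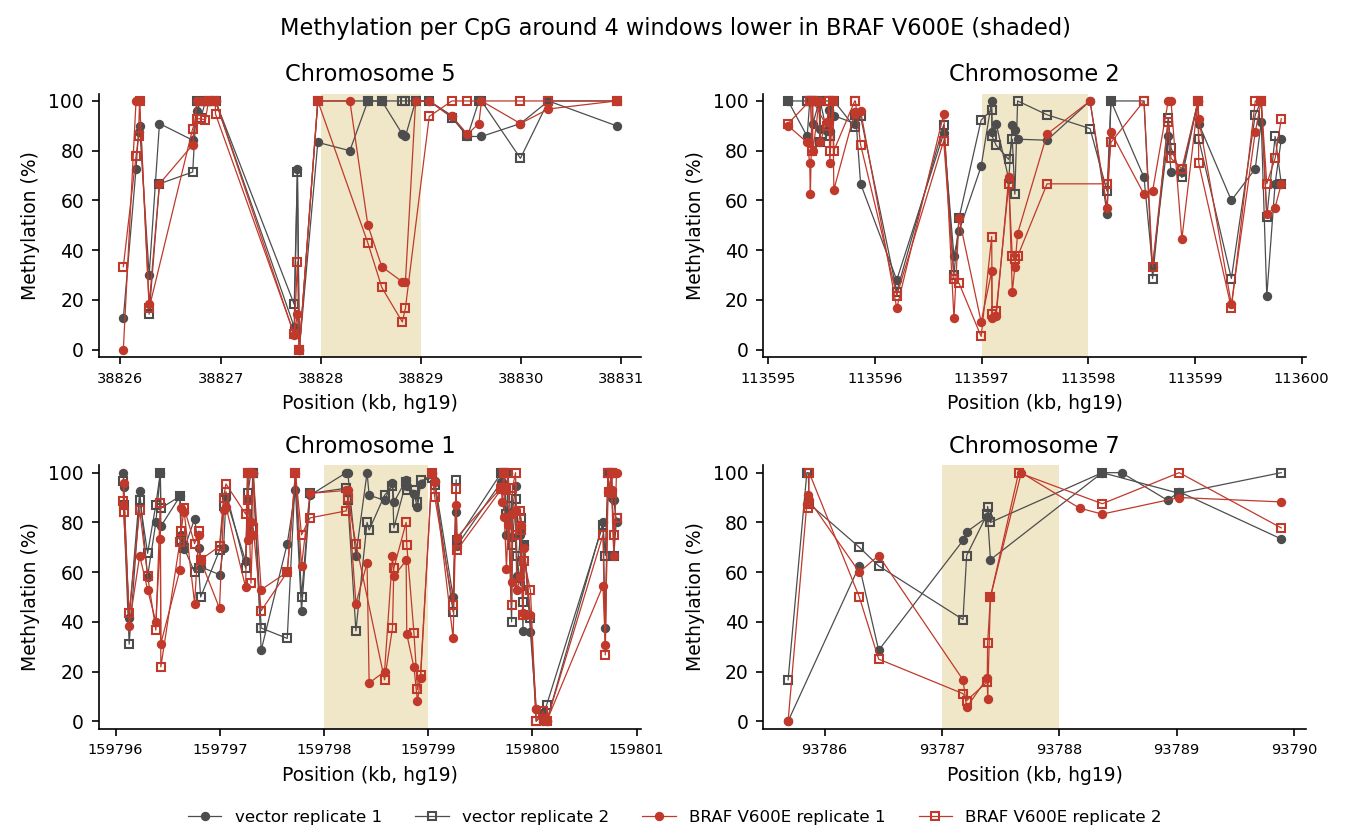
Methylation per CpG in percent against hg19 position in kb, for CpGs with at least 5 calls in a library, in 4 windows lower in BRAF V600E (shaded) and 2 kb on either side; lines join the CpGs of 1 library. In the shaded windows the BRAF V600E libraries lie below the vector libraries at several neighbouring CpGs, and single CpGs outside them also differ between the groups.

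Among the 10 windows with the largest gain, 3 also passed the threshold with each CpG weighted alike. A window of 65 CpGs on chromosome 4 (185887001 to 185888000) rose from 41.3% ± 14.5 to 71.8% ± 3.17 (SD, n = 2 each, 131 to 219 calls, adjusted p = 0.0203). A window of 30 CpGs on chromosome 3 (105601001 to 105602000) rose from 44.4% ± 4.51 to 70.7% ± 4.61 (284 to 531 calls, adjusted p = 6.3e-05) and covers the chromosome 3 cluster described above. A window of 14 CpGs on chromosome 9 (133895001 to 133896000) rose from 18.4% ± 1.47 to 38.3% ± 0.946 (131 to 248 calls, adjusted p = 0.0403). The other 7 lost the call under equal weighting, where the differences were 0.739 to 9.09 points on chromosomes 2, 15 and 16 and 10.6 to 16.6 points in the other 4. They lay on chromosome 2 (228336001 to 228337000, 30.6% ± 0.154 and 51.3% ± 16.8), chromosome 15 (51199001 to 51200000, 55.2% ± 1.74 and 73.0% ± 2.46), chromosome 16 (420001 to 421000, 17.8% ± 1.45 and 35.6% ± 1.66), chromosome X (153284001 to 153285000, 36.4% ± 3.68 and 53.3% ± 6.24, and 49092001 to 49093000, 47.5% ± 5.38 and 64.1% ± 7.66), chromosome 7 (152063001 to 152064000, 51.1% ± 1.94 and 67.5% ± 4.89) and chromosome 18 (31400001 to 31401000, 43.2% ± 2.22 and 59.4% ± 0.059). The difference on chromosome 2, 20.7 points, was 8.82 without BRAF V600E replicate 1 and 32.5 without BRAF V600E replicate 2, and that on chromosome 4, 30.5 points, was 20.2 without vector replicate 2.

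The lower windows were concentrated in highly methylated domains. Of the 195, 154 (79.0%) lay in such domains against 43.2% of the 2142189 tested windows with a mean level from 5 to 95%, in which a difference of 10 points was possible (Fisher's exact test, odds ratio 4.94, adjusted p = 2.284e-23). Only 10 (5.13%) lay in partially methylated domains, which held 37.1% of those windows (odds ratio 0.0917, adjusted p = 1.127e-24). This background was not matched to the called windows for level, CpG number, calls or replicate spread. Each of these bears on whether a window could be called, so the placement cannot be told apart from the calling rule. Clusters with a level under 10% overlapped 12 of the 195 lower windows (6.15%, against 0.756% of the background; adjusted p = 1.034e-07) and 12 of the 38 higher windows (31.6%; adjusted p = 3.74e-16). None of these 24 windows was called with each CpG weighted alike, and with CpGs matched the median difference went from -10.8 to -1.30 points in the 12 lower and from 14.1 to 0.927 points in the 12 higher windows. More than 2 kb from any such cluster lay 170 of the 195 lower windows (87.2%), fewer than the 96.7% of the background (odds ratio 0.230, adjusted p = 2.079e-08). Windows are not independent replicates, and 24 tests of placement were made, none of them planned. Windows with 20 or more CpGs made up 37 of the 38 higher windows and 53 of the 195 lower ones, against 10.5% of the background. In the divisions of the libraries across the groups, 29 of 29 and 115 of 122 called windows had 20 or more CpGs, against 90 of the 233, and 44.8% and 54.1% lay in highly methylated domains.

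The windows next to the lower windows showed little of their difference. Losses narrower than 1 kb and chance differences of single windows would both give this. In the windows directly next to the lower windows, leaving out 4 with over 2 times the calls in BRAF V600E, the median difference was -0.424 points (quartiles -3.08 and 1.18, 361 windows), and 56.5% were lower in BRAF V600E against 49.3% of all tested windows (exact binomial test, adjusted p = 0.0718 over 10 comparisons). At a distance of 3 kb the median was 0.0298 points. In windows of 5 kb, a size that was not simulated, the test called 0 of 562769, with 23691 at an unadjusted p under 0.05. In windows of 500 bp it called 78, of which 75 were lower. In simulated data the test of 1 kb windows recovered 14% of those lowered by 20 points and 56% of those lowered by 40 points. Limma on log2 ratios recovered 0 of the simulated windows at any size, so its count of 0 carries no information.

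**Figure D4:**
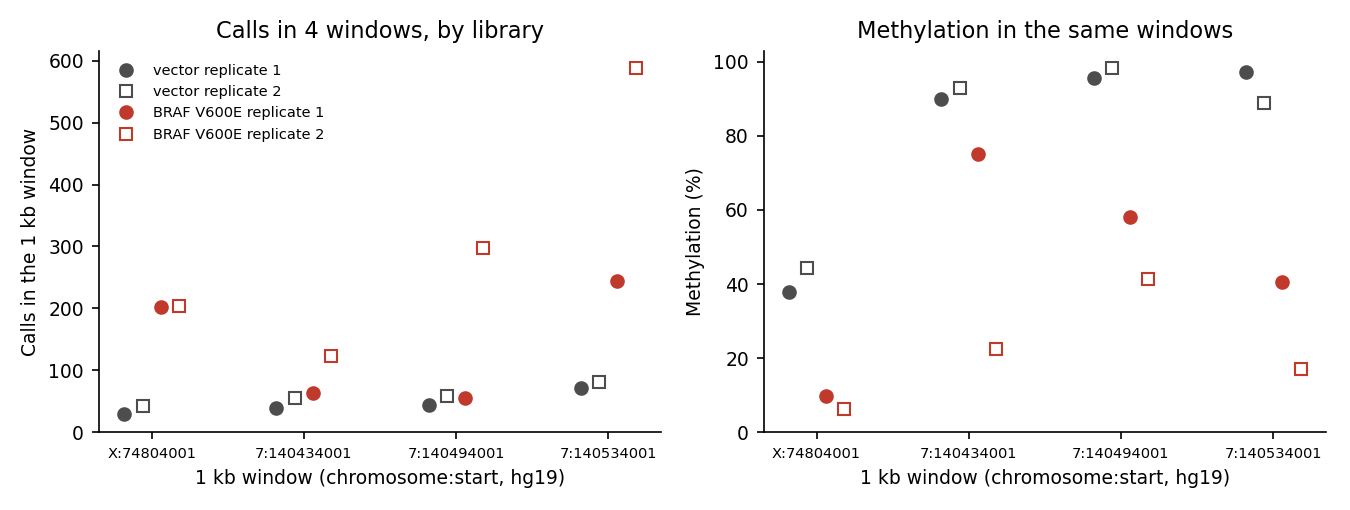
Calls per library (left) and methylation in percent (right) in the 4 windows of 1 kb past the threshold in which BRAF V600E libraries held over 2 times the depth-scaled calls of vector libraries; each point is 1 library. Calls reach 588 in BRAF V600E replicate 2 at 140534001 on chromosome 7, against 71 and 81 in the vector libraries, and methylation is lower in both BRAF V600E libraries in all 4 windows.

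Across the genome the libraries differed by similar amounts within and between the groups. Over 1734373 windows with at least 50 calls in each library, Pearson's r across windows was 0.969 between the vector libraries, 0.966 between the BRAF V600E libraries and 0.966 to 0.969 between libraries of different groups. The median absolute difference was 2.89 points between the vector libraries, the lowest of the 6 pairs, 3.13 points between the BRAF V600E libraries, the highest, and 2.95 to 3.09 points between the groups.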

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

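The tests in this part were chosen after the calls in these windows had been seen. The ratio of calls between the groups, which no comparison of methylation levels tests, was raised in the BRAF V600E libraries in 4 of the 233 windows past the threshold. Depth-scaled calls in BRAF V600E over vector libraries were 6.58 at 140534001, 4.14 at 140494001 and 2.34 at 140434001 on chromosome 7, and 6.65 at 74804001 on chromosome X. No other window past the threshold was above 1.69. The chromosome X window (74804001 to 74805000, 3 CpGs) had 29 and 43 calls in the vector libraries and 202 and 204 in the BRAF V600E libraries, and methylation there was 37.9% and 44.2% against 9.90% and 6.37% (adjusted p = 0.00981, limma-moderated model). At 140434001 calls per CpG relative to the library mean were 0.434 and 0.658 in the vector libraries, 0.831 in BRAF V600E replicate 1 and 1.72 in BRAF V600E replicate 2. Leaving out windows with over 2 times the calls in BRAF V600E gave 229 called windows, 191 lower and 38 higher. Across 8494176 windows of 200 bp with at least 5 depth-scaled calls in each library, 58 had over 4-fold more depth-scaled calls in both BRAF V600E libraries than in both vector libraries and 84 the reverse. The 58 include parts of the windows at 140534001 (ratio 8.69) and 74804001 (ratio 11.0), and none at 140494001 or 140434001.

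A candidate explanation is that reads from the introduced BRAF sequence, carried by the lentivirus and unmethylated, were placed at the cell's own copies of the sequence. The RefSeq table lists BRAF on chromosome 7 and a BRAF pseudogene, BRAFP1, on chromosome X, but the windows were not placed in genes here. The calls in excess of the vector libraries were 1.27% to 26.4% methylated in the 4 windows, but these windows were picked as lower in BRAF V600E, so a low share was bound to follow and the explanation stays open. At 140494001 BRAF V600E replicate 1 had 0.612 times its mean calls per CpG against 0.409 and 0.595 in the vector libraries. It measured 58.2% there against 95.5% and 98.3%. The vector libraries differ too much in depth at this window to tell whether added calls account for that value. Collapsed repeats would raise the vector libraries too, and the mean of the 2 vector libraries was at most 0.820 times their mean calls per CpG in the 4 windows (1.01 in the highest single library), which argues against repeats.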

How the results depend on the processing

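Among the alternatives, equal weights per CpG for windows, clusters and bins, thinning and crossed pairing were chosen after seeing the data. So were dispersions with a trend in depth, removal of windows with excess calls and the lambda correction. The planned tests of promoters, gene bodies, gene lists and BRAF exons were not run. The group differences, not the levels, of CpG-dense clusters and partially methylated domains moved by less than the replicate SD under the alternatives run. In this design leaving out 1 library cannot move a difference by more than that SD, and the replicate block leaves it unchanged. Those settings could therefore not show a move. With 1 library left out the differences were -0.188 to 0.175 and -0.755 to 0.337 points, with both signs in each. The genome-wide difference, 0.406 points, was 0.0469 with equal weight per CpG, 0.187 over CpGs with at least 10 calls in every library, 0.374 without deep CpGs, 0.319 with X added and 0.421 with the lambda correction. In highly methylated domains 0.255 became 0.00878 with equal weight per CpG and 0.106 in bins of 10 kb. It was 0.0426 without BRAF V600E replicate 2, 0.467 without BRAF V600E replicate 1, 0.133 without vector replicate 2 and 0.377 without vector replicate 1. Called 1 kb windows, 233 in all, numbered 104 at 20 points or more, 134 with at least 10 calls per library, 345 (273 lower, 72 higher) with at least 50, 78 in windows of 500 bp, 0 in windows of 5 kb, 0 with limma on log2 ratios, 119 with each CpG weighted alike (115 lower, 4 higher) and 0 to 1 with 1 library left out. With every library thinned to equal calls 0 were called, where the prior degrees of freedom of the dispersion dropped from 30.4 to 2.65 and the median difference of the 195 lower windows was -20 against -20.6 points. The edgeR model called 6 clusters and 58 bins against 0 and 0. Leaving out 1 library gave 0 to 356 bins and 0 clusters each time. Where 1 library was left out, the lone library was assumed to vary like the other group. With the genome-wide difference set to 0 the windows divided into 30 higher and 230 lower. With at least 10 calls per library they divided into 18 higher and 116 lower. Dispersions squeezed towards a trend in depth gave 19 higher and 162 lower. The cause of these moves was not tested beyond the values given.

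With the replicate number as a block the model called 0 windows, 0 clusters and 57 bins, all 57 higher in BRAF V600E, and the genome-wide difference was 0.406 ± 0.012 points (SD of 2 pairs). For clusters the blocked difference was -0.00665 ± 0.384 points, for partially methylated domains -0.209 ± 1.13 and for highly methylated domains 0.255 ± 0.473. The libraries share only a number: deviations of same-numbered libraries correlated at -0.00367 across windows, -0.0177 across clusters and -0.376 across bins. Crossed pairing called 0 windows, 0 clusters and 1 bin. Of the 20 named windows, 16 of the 16 with at least 50 calls in each library kept the call at that minimum and 13 of 20 at a minimum of 10 calls. The higher minimum leaves a window's own calls as they are and tests fewer windows, so it was a weak check. With the replicate block all 20 lost the call. At this depth and number of libraries the quasi-binomial model recovered 0% of simulated windows lowered by 10 points, a rate that the 10-point cutoff also limits, and 14% of those lowered by 20.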

Other observations

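The tests of adjacent windows, thinning and blocked bins were written down before their results were seen, and the others in this part after. Mitochondrial DNA, which was not part of any comparison, gave 8.73 and 7.71 calls per 1000 autosomal calls in the vector libraries and 7.39 and 7.01 in the BRAF V600E libraries (8.22 ± 0.720 and 7.20 ± 0.270, SD, n = 2 each; exact permutation p = 0.333, the smallest possible). The calls there were 0.454% and 0.321% methylated in vector and 0.400% and 0.327% in BRAF V600E libraries, close to the unconverted share of lambda in the same libraries.

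Uneven coverage of CpGs within a window would remove the difference once CpGs are matched: the 12 lower and 12 higher windows that overlap clusters under 10% kept a median of 11.6% and 6.59% of it, as this cause would give, while the other 183 lower and 26 higher windows kept 97.4% and 81.8%, which argues against it as the whole cause there. Incomplete conversion cannot account for losses of 20 points, since unconverted lambda differed by 0.143 points at most. Chance differences of single windows stay open, as adjacent windows had a median of -0.424 points beside lower and -0.109 points beside higher windows, values that losses narrower than 1 kb would also give. Thinning to equal depth left 0 windows called but a median difference of -20 in the 195 lower windows against -20.6 points, with prior degrees of freedom of 2.65 against 30.4, so the lost calls do not point to depth and do not exclude it. There are 3 splits of the 4 libraries, too few for a share under 0.05: 1 of the 3, the real one with 233 windows, reached that count, and the highest other gave 122; a biological effect of BRAF V600E stays open, untested.

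The slightly higher share of methylated calls in BRAF V600E may come from fewer calls in CpG-dense DNA, which is largely unmethylated. With every CpG weighted alike the difference was 0.0469 points, under the replicate SD of 0.156. The bins that were higher with a replicate block, 57 by calls, numbered 0 with each CpG weighted alike in the same blocked model. Uneven coverage would give this, but the weighting also cut each CpG to its lowest depth. Bins at an unadjusted p under 0.05 in the blocked model numbered 496 of 28467, against 1891 by calls. Lost power could thus also give 0, and the count does not decide between them. What made the coverage of the libraries differ was not tested.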
